A study of Mus musculus with 8 samples.

How the data were processed

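ATAC-seq libraries of 2 derivatives of a mouse liver metastasis line, a control knockdown and a Blimp1 knockdown, each cultured at 0.5% or 20% oxygen for 24 hours, were compared from a deposited table of insert counts per peak. Samples were grouped by their titles into 4 groups with 2 libraries each, and each column was matched to a sample by the library name in its label. The submitters' processing notes name cutadapt, Bowtie2 and MACS2 and the mm9 build; their versions, the peak-calling settings, whether peaks were called on pooled libraries, the treatment of duplicates and the shift of reads to the transposase cut site are not given in the sources used here. The authors deposited counts of inserts, whole numbers that were not normalized, for 74148 peaks that do not overlap (width 150 to 3633, median 574), each with a gene symbol. How peaks were assigned to genes, how an insert was defined and whether positions count from 0 or 1 is not stated, so positions are printed as deposited and "at" a gene means the symbol in the table. Inserts outside peaks, exon and intron annotation and sequence of that build were not used here. Of 18245 symbols, 17493 matched a current symbol and 18179 a current symbol or synonym of the GRCm38 RefSeq gene table, which was used for names only. 22 symbols (162 peaks) stood as dates in the table; these peaks were tested without a usable name. Every sample column of the table was used (0 unused).

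Totals per library were 8965020 and 10417994 (control, 20% oxygen), 6862664 and 8520733 (control, 0.5%), 7680363 and 6783406 (knockdown, 20%), and 9673903 and 6108229 inserts (knockdown, 0.5%). The libraries of a group differed by more than independent counting noise (chi-square per degree of freedom 1.124 to 1.441 over peaks with a pair sum of at least 20). They were therefore not one set of counts deposited again. Since the definition of an insert is not stated, 1 library sequenced again is not excluded. Each gave up to 32 peaks with a count of 0.

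Since the labels call the libraries of a group technical replicates, the oxygen effect over both lines and the knockdown effect over both oxygen levels were tested on 4 sums, one per culture, in an additive model with 1 residual degree of freedom. Its error comes from the difference of one effect between the levels of the other, taken over many peaks, so interaction adds to it. The dispersion (trended median 0.00826) was shared across peaks, and the estimated prior degrees of freedom were infinite. A peak's own difference between lines or levels therefore did not set its error, and its p-value does not measure its own spread between cultures. The single contrasts and the interaction were fitted on all 8 libraries with a mean per group (4 residual degrees of freedom, trended dispersion 0.00252); their p-values measure only the spread between technical libraries and are too small as a measure of cultures. All used edgeR 4.0.16 (filterByExpr, TMM, glmQLFit robust, glmQLFTest, prior count 2) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05; "rose", "fell", "higher" and "lower" mean called at that level. CPM are inserts scaled by the TMM-adjusted library total. Errors of fold changes are SEs derived from the test's F statistic.

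Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) over the peaks of their genes, with Benjamini-Hochberg adjustment over the 16 lists. The lists were HIF targets, glycolysis, cell cycle and DNA replication, interferon response and antigen presentation, Blimp1 targets in lymphocytes, epithelial, mesenchymal and EMT, pancreatic and foregut lineage, AP-1 and immediate early, NF-kB and inflammatory, unfolded protein response and amino acid stress, oxidative phosphorylation and mitochondrial biogenesis, and haematopoietic, endothelial, fibroblast and stellate, and hepatocyte markers. They hold 389 genes in 395 memberships, of which 350 genes had a peak. Peaks of one gene are not independent, which the preset correlation covers only in part. With an estimated correlation the test takes the residual degrees of freedom of the fit, 1 on the sums and 4 on the 8 libraries. It then has little power. The motif tests and the promoter-only and distance-limited assignments that were planned were not run, since no sequence or annotation of the build was used here, and peaks were taken for the table's gene at any distance.

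The rule for naming peaks, the lists and the first set of alternatives below were fixed before the data were examined. Named were the 10 peaks with the smallest p each way for the 2 main comparisons, among called peaks that moved the same way in both lines or levels, and 5 each way for the single contrasts and the interaction, with a gene named once by its first peak. The 4 peaks with the smallest p per list in the main comparisons, where a gene could recur, and any peak of Prdm1, Vegfa, Slc2a1, Car9 and Hmga2 were added. Alternatives were RLE scaling, total-insert scaling, cyclic loess with limma, no filter, a mean of at least 50 inserts, DESeq2 1.42.0, an adjusted p of 0.01, an absolute log2 fold change of at least 1, other units of replication, the replicate number as a block, an estimated correlation and leaving out each library. Added after seeing the data were removing the median shift of each 2 Mb bin or chromosome as an offset, thinning to the smallest total, leaving out chromosome 18, and list tests with loess or with a correlation estimated on all 8 libraries. Bins needed at least 20 tested peaks. Strength is the fitted mean log2 CPM.

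The fits were tested on counts simulated from the real means with 200 changed peaks among 73375. In the oxygen comparison the sums recovered 75.8% of peaks changed 2-fold, 29.9% of those changed 1.5-fold and 4.48% of those changed 1.25-fold, with 6 false calls among 79. In the knockdown comparison these were 74.2%, 25.4% and 2.99%, with 5 false calls among 73. In the contrast within the control line the 8 libraries recovered 65.2%, 26.9% and 7.46%, with 2 false calls among 68. In the data 43.1% of tested peaks were called for oxygen and 11.7% for the knockdown, so the adjusted threshold was stricter in the simulation. These shares therefore do not carry over to the data, where a 1.22-fold oxygen change at a Prdm1 peak was called. Depth was not varied. Figures were drawn with matplotlib.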

Results

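Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in derivatives of a cell line from a liver metastasis in a mouse with mutant Kras and p53 alleles and a Cre driver of the pancreas. One derivative carried a control knockdown and the other a knockdown of Blimp1, the transcriptional repressor encoded by Prdm1. Each was cultured at 0.5% or 20% oxygen for 24 hours. The 4 groups had 2 libraries each, which the labels call technical replicates, so the 8 libraries stood for 4 cultures and the SDs below (n = 2 libraries) are the spread between libraries of one culture. The table of 74148 peaks held between 6108229 inserts (Blimp1 knockdown at 0.5% oxygen, replicate 2) and 10417994 inserts (control at 20% oxygen, replicate 2) per library, with a median of 48 to 78 inserts per peak. Libraries of one group had Spearman correlations of 0.976 to 0.981 across peaks. These were 0.95 to 0.956 between the lines at one oxygen level and 0.913 to 0.921 between oxygen levels in one line. Peaks are not independent replicates. Peak positions are those of the deposited table, in mm9.

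The first comparison asked which sites opened or closed at low oxygen on average over both lines. Accessibility rose at a peak assigned to Tyw3, an enzyme of tRNA modification (chromosome 3, 154291113 to 154291928), from 9.57 ± 2.1 to 45 ± 0.91 CPM in the control line and from 11 ± 2.9 to 41.3 ± 6.7 in the Blimp1 knockdown line (mean ± SD, n = 2 libraries; CPM are inserts scaled to the TMM-adjusted library total). It also rose at Egfl7, a protein secreted by endothelial cells (chromosome 2, 26428052 to 26429241), from 20 ± 1.6 to 56.7 ± 1.1 and from 19.6 ± 1.1 to 62.8 ± 8.3 CPM. It fell at Alyref2 (chromosome 1, 173431542 to 173432173) from 52 ± 2.2 to 14.9 ± 1.1 in the control line and from 64.9 ± 3.9 to 15.8 ± 1.3 in the knockdown line. At Dhrs3, a retinal reductase (chromosome 4, 144539147 to 144540176), it fell from 69.6 ± 8 to 20.3 ± 0.47 and from 60.9 ± 2.6 to 18.3 ± 2.5. Over the 73868 peaks tested, 15201 were higher and 16663 lower at 0.5% oxygen by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. They were assigned to 8154 and 7253 genes. With an absolute log2 fold change of at least 1, 3359 were higher and 1404 lower. The error of this test was shared across peaks, so its p-values do not measure a peak's own spread between cultures.

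The 10 rising peaks with the smallest p were assigned to Tyw3 (log2 fold change 2.08 ± 0.13, SE, adjusted p = 1.7e-51), Egfl7 (1.62 ± 0.11), Mir5098 (2.31 ± 0.17), Pou4f2, a transcription factor of retinal neurons (1.80 ± 0.13), Jam2, a junctional adhesion molecule (2.24 ± 0.17), Camsap1, a microtubule-binding protein (2.45 ± 0.19), Zfp462 (2.65 ± 0.21), Cacng3, a calcium channel subunit (2.56 ± 0.20), Thap1 (2.34 ± 0.19) and D030024E09Rik (1.84 ± 0.15). The 10 falling peaks were assigned to Alyref2 (log2 fold change -1.91 ± 0.12, SE, adjusted p = 1e-55), 2610035D17Rik (-2.17 ± 0.13), Dhrs3 (-1.76 ± 0.11), 1700028E10Rik (-1.28 ± 0.08), Trappc6b, a vesicle-tethering subunit (-1.40 ± 0.09), Cyb5a, cytochrome b5 (-1.91 ± 0.12), Plk2, a polo-like kinase (-1.79 ± 0.12), Snap25, a SNARE protein of neurons (-1.41 ± 0.09), N4bp2l2 (-1.25 ± 0.08) and Mir6390 (-1.30 ± 0.09). Part of these falls was shared by their regions: after the median of each 2 Mb bin was removed, the log2 fold change was -0.34 at 1700028E10Rik, -0.46 at N4bp2l2, -0.89 at Snap25, -1.24 at Cyb5a and -1.42 at 2610035D17Rik, all still called. With loess it was -0.70 at 1700028E10Rik, -0.71 at N4bp2l2, -0.93 at Trappc6b and -0.84 at Mir6390. DESeq2 called 10611 peaks in this comparison, 3865 higher and 6746 lower. Scaling to total inserts moved the median log2 fold change of the tested peaks from 0.00 to 0.15 and gave 21227 higher and 11245 lower peaks, so directions are given relative to the TMM-scaled median.

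**Figure D1:**
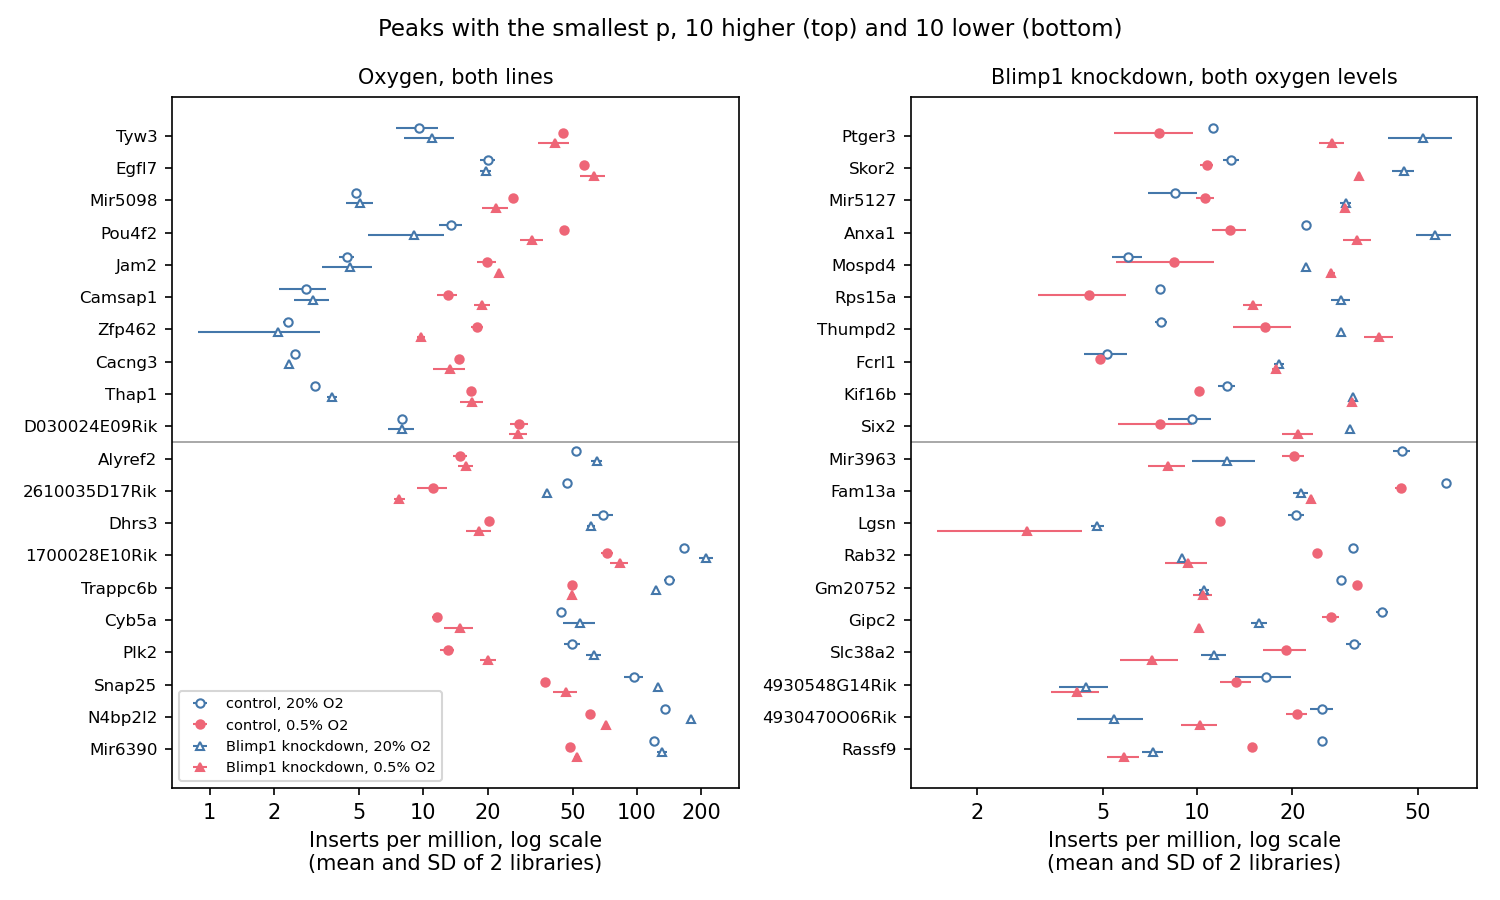
Accessibility of the peaks with the smallest p for oxygen (left) and for Blimp1 knockdown (right), 10 higher above the line and 10 lower below it, as CPM on a log axis. Points are means and bars SDs of 2 libraries per group. At Tyw3 the 0.5% oxygen groups sat at 45 and 41.3 CPM and the 20% oxygen groups at 9.57 and 11.

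Among the gene lists fixed in advance, epithelial genes had the smallest p for oxygen. Of 131 tested peaks at 25 epithelial genes, 52 rose and 8 fell at 0.5% oxygen, and the list's median log2 fold change was 0.33 (camera, adjusted p = 9.9e-06 with the preset correlation and 0.64 with one estimated from the 4 sums). Rising peaks lay at the adhesion gene Cdh1 (log2 fold change 1.46 ± 0.18, SE), the tight junction gene Tjp1 (1.56 ± 0.20), the epithelial transcription factor Elf3 (1.51 ± 0.19) and the mucin Muc1 (1.38 ± 0.18). Fibroblast and stellate cell markers had 23 rising peaks and 1 falling peak of 56 (median 0.37, adjusted p = 0.00071, or 0.64 with the estimated correlation), among them peaks at the collagen gene Col5a1 (1.47 ± 0.17) and at Tcf21 (1.31 ± 0.21). NF-kB and inflammatory genes had 57 rising and 23 falling peaks of 163 (median 0.28, adjusted p = 0.0052, or 0.64 estimated). A peak at the cytokine gene Csf1 rose (1.31 ± 0.16), while peaks at Nfkb1 (-0.88 ± 0.10) and at the prostaglandin synthase gene Ptgs2 (-0.90 ± 0.13) fell. Known Blimp1 targets in lymphocytes had 33 rising and 8 falling peaks of 90 (median 0.29, adjusted p = 0.0052, or 0.64 estimated), with rises at Bcl6 (1.23 ± 0.17) and Id3 (2.42 ± 0.42, at under 3 CPM in each group and with no adjusted p from DESeq2). Haematopoietic markers had 16 rising and 2 falling peaks of 32 (median 0.36, adjusted p = 0.017, or 0.64 estimated), and AP-1 and immediate early genes 87 rising and 43 falling peaks of 265 (median 0.14, adjusted p = 0.046, or 0.79 estimated). At the latter, a peak at Egr1 rose from 6.47 ± 0.81 to 15.7 ± 1.5 CPM in the control line and from 7.4 ± 0.083 to 23.8 ± 1.5 in the knockdown line, and peaks at Jun (-0.85 ± 0.08), Cyr61 (-0.74 ± 0.09) and Dusp6 (-0.74 ± 0.10) fell. After regional medians were removed, the log2 fold change was -0.44 at Jun, -0.26 at Cyr61, -0.29 at Dusp6, -0.50 at Nfkb1 and 0.87 at Muc1, and with loess -0.26, -0.27 and -0.41 at Jun, Cyr61 and Dusp6 and -0.49 at Nfkb1, all still called. With the estimated correlation no list passed, but that test had only the 1 residual degree of freedom of the sums. The estimated correlation was -0.018 for fibroblast markers, -0.028 for haematopoietic markers and 0.0012 for Blimp1 targets, all below the preset 0.01. It was 0.056 for epithelial, 0.031 for AP-1 and 0.021 for NF-kB genes. The fits of all 8 libraries gave other estimates. These were 0.057 (control line) and 0.081 (knockdown line) for haematopoietic markers, but 0.0024 and 0.0083 for NF-kB genes. For fibroblast markers they stayed below 0 (-0.014 and -0.017), so that loss is not read as correlation between peaks. For the other lists correlation and the few degrees of freedom cannot be told apart. Over both lines no list passed after the median shift of each 2 Mb bin was removed. The adjusted p (camera) was then 0.11 for epithelial genes and haematopoietic markers, 0.26 for NF-kB, 0.36 for Blimp1 targets and AP-1, and 0.6 for fibroblast markers.

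The other 10 lists did not pass. Targets of HIF, the oxygen-regulated transcription factor, had 58 rising and 48 falling peaks of 227 (median 0.03, adjusted p = 0.76), and 23 of their genes had a rising and 23 a falling peak. Vegfa had 4 rising and 0 falling peaks of 9, the first by p at 0.91 ± 0.14 (log2 fold change, SE), and DESeq2 called 2 of the 4. Slc2a1, the glucose transporter, had 0 rising peaks and 1 falling peak of 7 (-0.63 ± 0.11), and Car9 had 1 rising peak of 2 (0.52 ± 0.21, adjusted p = 0.036). The Car9 call was lost with DESeq2, loess and regional correction, and without control replicate 2 at 20% oxygen (0.47), knockdown replicate 1 at 20% (0.46) or knockdown replicate 2 at 0.5% (0.48). The HIF target peaks with the smallest p fell: Bhlhe40 (-0.83 ± 0.08), the prolyl hydroxylase gene Egln1 (-1.22 ± 0.12 and -0.99 ± 0.10) and the collagen-modifying enzyme gene Plod2 (-0.84 ± 0.10). Glycolysis genes had 11 rising and 20 falling peaks of 71 (median -0.13, adjusted p = 0.71), with Hk1 rising (1.36 ± 0.22) and Pgm2 falling (-0.72 ± 0.10). Pancreatic and foregut lineage genes had 20 rising and 43 falling peaks of 132 (median -0.20, adjusted p = 0.095); Foxa2 (-0.75 ± 0.09) and Sox9 (-0.87 ± 0.11) fell, while Gata4 (1.34 ± 0.17) and Foxa1 (1.34 ± 0.18) rose. The Sox9 change was -0.12 once regional medians were removed, and the call was lost. The change was then -0.42 at Bhlhe40, -0.34 at Pgm2, -0.40 at Foxa2 and -0.40 at Slc2a1, and with loess -0.22, -0.40, -0.32 and -0.39, with -0.50 at Plod2, all still called. Cell cycle genes had 25 rising and 34 falling peaks of 125 (adjusted p = 0.71; median -0.06, mean 0.01, test toward lower), mesenchymal genes 28 and 22 of 130 (0.71), interferon and antigen presentation genes 25 and 19 of 79 (0.83; median -0.05, mean 0.02, test toward higher), and unfolded protein response genes 26 and 27 of 114 (0.83). Oxidative phosphorylation genes had 13 rising and 18 falling peaks of 81 (adjusted p = 0.76), endothelial markers 12 and 22 of 76 (0.2), and hepatocyte markers 9 and 7 of 55 (0.77). Adjusted over the list alone, the rising and falling counts were 53 and 8 for epithelial genes, 24 and 2 for fibroblast markers, 58 and 24 for NF-kB, 33 and 10 for Blimp1 targets, 16 and 2 for haematopoietic markers, 89 and 45 for AP-1, 58 and 49 for HIF targets, 11 and 20 for glycolysis and 20 and 44 for pancreatic genes. They were 25 and 34 for cell cycle, 27 and 22 for mesenchymal, 25 and 21 for interferon, 26 and 27 for unfolded protein response and 12 and 18 for oxidative phosphorylation genes, 12 and 22 for endothelial and 9 and 7 for hepatocyte markers.

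**Figure D2:**
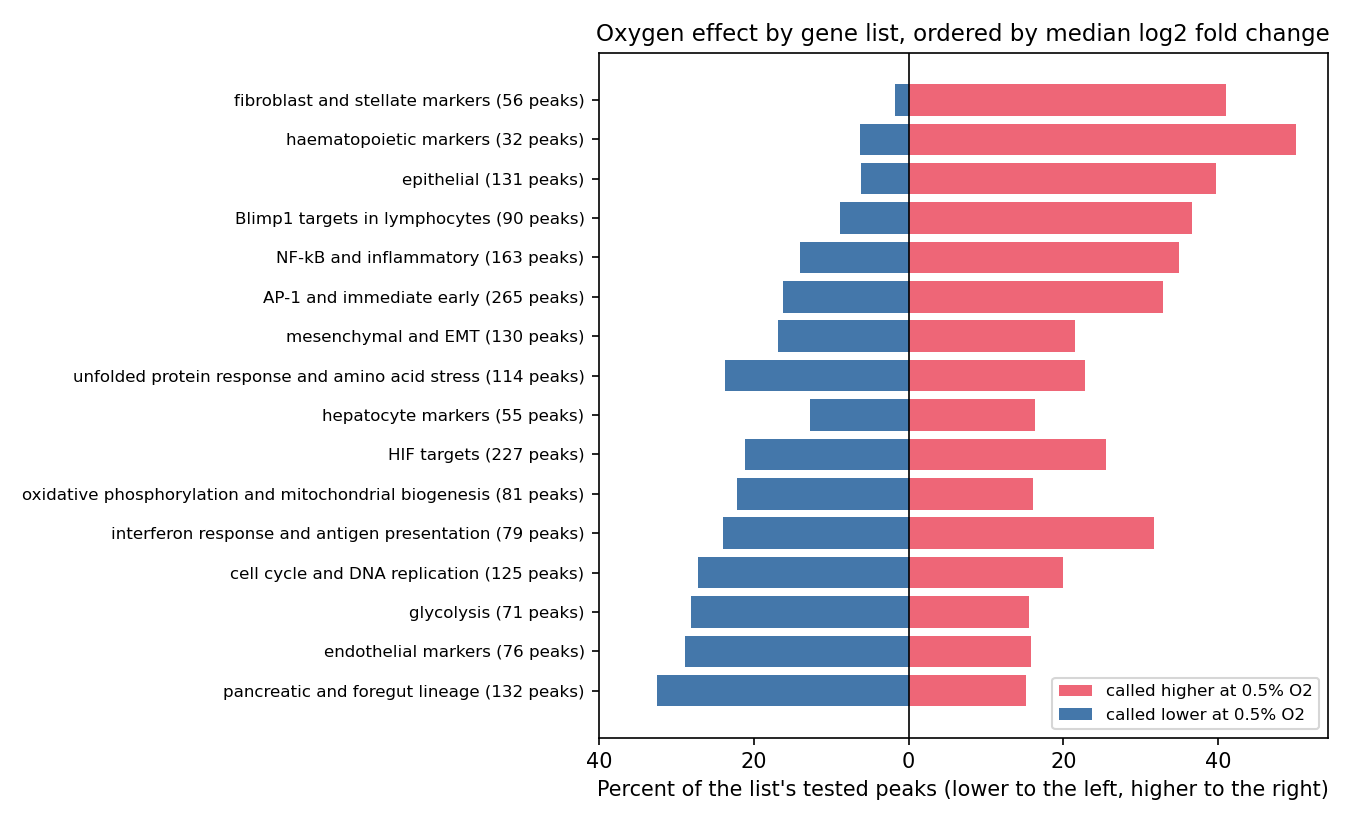
Share of each list's tested peaks, in percent, called higher (right) or lower (left) at 0.5% oxygen over both lines, with lists ordered by median log2 fold change. Fibroblast markers (23 higher, 1 lower) stand at the top and pancreatic lineage genes (20 higher, 43 lower) at the bottom.

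The oxygen effect moved with peak strength and with position. Of 10 classes of peak strength, the weakest had a median log2 fold change of 0.30 and the strongest -0.35, and the Spearman correlation of fold change with strength across peaks was -0.35 in the control line and -0.19 in the knockdown line. The strongest 10% of peaks held 40.3 to 41.1% of the inserts of the 20% oxygen libraries and 34.7 to 36.2% of those of the 0.5% oxygen libraries. Whole regions shifted together: of 1068 bins of 2 Mb with at least 20 peaks tested in the fits of all 8 libraries, 106 had a median above 0.3 and 197 a median below -0.3. The lowest lay on chromosome 5 from 152000001 to 154000000 (median -0.97, with 18 of 20 peaks called lower), and the highest on chromosome 19 from 2000001 to 4000000 (0.70, with 33 of 42 called higher). After the median of each 2 Mb bin was removed, 18874 of the 31864 oxygen calls kept their direction and passed, and the split became 12770 higher and 11712 lower. The bin medians fell from 0.10 in class 2 to -0.34 in class 10 of 10 equal parts of the chromosomes' coordinates. Their Spearman correlation with position was below 0 in 20 of 20 chromosomes, from -0.061 on chromosome 11 to -0.9 on chromosome X. A trend with position was not particular to oxygen, though that of the knockdown effect at 20% oxygen was smaller. Its class medians ran from -0.09 in class 6 to 0.12 in class 10, and it shares its cultures with the oxygen effect. The bin medians of the knockdown effect at 20% oxygen had a Spearman correlation of 0.27 with position, below 0 in 3 of 20 chromosomes. At 0.5% oxygen it was -0.03, below 0 in 11 of 20.

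**Figure D3:**
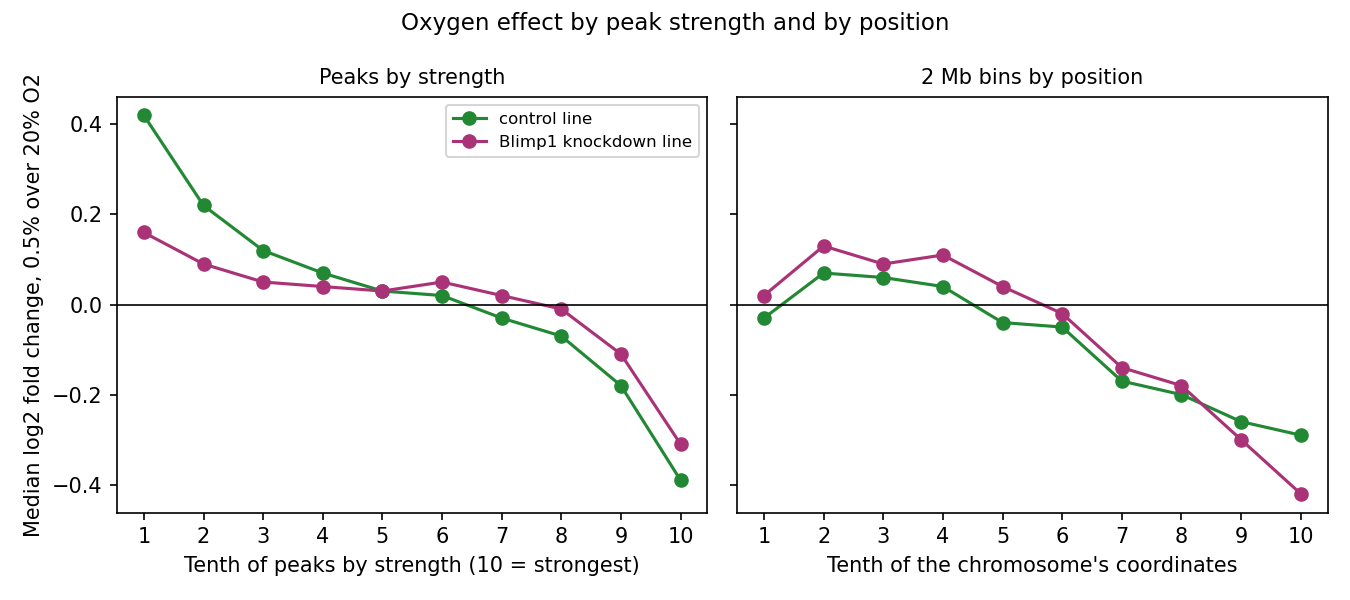
Median log2 fold change of 0.5% over 20% oxygen in each line, by 10 classes of peak strength (left) and 10 parts of the chromosome's coordinates for 2 Mb bins (right). In the control line it ran from 0.42 in the weakest to -0.39 in the strongest peaks, and in the knockdown line it reached -0.42 at the far end of the chromosomes.

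Within each line, the single contrasts asked whether the oxygen response was alike in the control and the Blimp1 knockdown line. Their p-values measure the spread between technical libraries only. In the control line 14465 peaks rose and 17378 fell of 73416, and in the knockdown line 13308 rose and 15746 fell. DESeq2 called 16226 and 15104 peaks, and an absolute log2 fold change of at least 1 turned the splits to 4209 higher and 1692 lower in the control line and 3529 and 2377 in the knockdown line. The lines shared 8594 rising peaks (2622 expected of independent lists) and 11566 falling peaks (3727 expected). This expectation takes every peak as equally likely to be called. In the control line 4859 of the strongest 10% of peaks fell, against 95 of the weakest 10%. The excess therefore does not measure agreement at single sites alone. Peaks called over both lines had a median log2 fold change of 0.72 in the control line and 0.70 in the knockdown line where they rose, and of -0.62 and -0.60 where they fell. These peaks were selected for their effect over both lines, which favours like medians. Over all 73416 peaks the oxygen log2 fold changes of the lines had a Spearman correlation of 0.74, and 79% shared their sign. Besides peaks named above, the 5 with the smallest p each way included rises at Gm5468 in the control line (1.82 ± 0.13) and at the ephrin receptor gene Epha7 (1.43 ± 0.10), Tmem106b (1.48 ± 0.11) and the DNA polymerase subunit gene Pold4 (1.51 ± 0.11) in the knockdown line. After regional medians were removed the Pold4 change was 0.84. Falls at the transcription factor gene Maf (-1.72 ± 0.10) and at Mir21c (-1.59 ± 0.10) were among the 5 in the control line. The 6 lists that passed over both lines passed in the control line (camera, highest adjusted p = 0.027, for AP-1), and 4 of them in the knockdown line, without haematopoietic markers (adjusted p = 0.059) and AP-1 (0.13). None passed with an estimated correlation, which left the test 4 degrees of freedom (camera, lowest adjusted p = 0.11 in the control and 0.17 in the knockdown line). After regional medians were removed, epithelial genes and haematopoietic markers passed in the control line (adjusted p = 0.046 each) and no list in the knockdown line (lowest adjusted p = 0.31). Scaled to total inserts, 21513 peaks rose and 11315 fell in the control line, and 18332 rose and 11170 fell in the knockdown line.

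The difference of the oxygen effect between the lines, tested itself, passed at 665 of 73416 peaks by edgeR, of which 445 had a more positive and 220 a more negative oxygen effect in the knockdown line. At Lrrn3, a neuronal leucine-rich repeat protein (chromosome 12, 42171693 to 42172601), accessibility was 26.5 ± 1.9 CPM at 20% and 19.1 ± 1.1 at 0.5% oxygen in the control line, against 10.7 ± 1.5 and 20 ± 3.4 in the knockdown line. At Tle4, a corepressor (chromosome 19, 14590078 to 14591413), it was 28.2 ± 1.3 and 23.1 ± 0.24 against 12.7 ± 1.8 and 23.9 ± 0.054. At Slc2a1 the log2 fold change with oxygen was -0.34 in the control line and -0.93 in the knockdown line (difference -0.59 ± 0.15, SE, adjusted p = 0.031), and that call was lost with DESeq2, after regional correction and without any 1 of the 8 libraries (-0.53 to -0.63). Of the 15 Prdm1 peaks, 0 passed this test (edgeR, lowest adjusted p = 0.37), and no gene list did (lowest adjusted p = 0.79). DESeq2 called 5 interaction peaks. The count was 36 or 234 without control replicate 1 or 2 at 0.5% oxygen, 147 without control replicate 2 at 20%, 399 or 124 without knockdown replicate 1 or 2 at 20%, and 129 or 1065 without knockdown replicate 1 or 2 at 0.5%. Scaling to total inserts gave 316 more positive and 262 more negative peaks, and loess 173 and 134. An absolute log2 fold change of at least 1 turned the split to 111 and 129. The difference moved with peak strength (Spearman 0.21), from a median of -0.26 in the weakest of 10 classes, with 0 more positive and 7 more negative calls, to 0.07 in the strongest, with 116 and 20.

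In the knockdown comparison, the summed CPM of the peaks assigned to Prdm1 was smaller in the knockdown line, though the sum was not tested. The 15 peaks summed to 251 ± 7.5 (20% oxygen) and 244 ± 8.9 (0.5% oxygen) CPM in the control line and to 211 ± 3 and 214 ± 1.3 in the knockdown line (mean ± SD, n = 2 libraries). Those called for oxygen or knockdown lay on chromosome 10 from 44139572 to 44443408, so not all need lie at the gene itself. Of these peaks 5 were lower with knockdown and 0 higher, the first by p at -1.36 ± 0.28 (log2 fold change, SE, adjusted p = 4.9e-05), for which DESeq2 gave no adjusted p; DESeq2 did not call the other 4. A short hairpin acts on the transcript, so accessibility at the locus does not check the knockdown. With oxygen, 4 Prdm1 peaks rose and 2 fell, from 1.01 ± 0.15 to -0.47 ± 0.16. DESeq2 called 2 of these 6, gave no adjusted p for 2 and did not call a rise of 0.29 and the fall of -0.47.

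Accessibility was higher in the Blimp1 knockdown line than in the control line at a peak of Ptger3, a prostaglandin E2 receptor (chromosome 3, 157351218 to 157351713), going from 11.2 ± 0.2 to 52.1 ± 12 CPM at 20% oxygen and from 7.55 ± 2.1 to 26.7 ± 2.4 at 0.5%. At Anxa1, an annexin (chromosome 19, 20313909 to 20314559), it rose from 22.1 ± 0.56 to 56.6 ± 7.1 and from 12.7 ± 1.6 to 32.2 ± 3.3. It fell at Fam13a (chromosome 6, 59057273 to 59058522) from 61.5 ± 0.45 to 21.3 ± 1.2 and from 44.2 ± 1.7 to 22.9 ± 0.48, and at Slc38a2, an amino acid transporter (chromosome 15, 96660205 to 96661397), from 31.3 ± 1.7 to 11.3 ± 1 and from 19.1 ± 3 to 7.19 ± 1.5. Of 73868 peaks tested, 4677 were higher and 3991 lower in the knockdown line (edgeR), against 31864 called for oxygen. Scaling to total inserts gave 3852 higher and 4225 lower, and an absolute log2 fold change of at least 1 gave 341 and 712. DESeq2 called 657 peaks, 408 higher and 249 lower. Each line was 1 derivative, so both oxygen levels compared the same 2 derivatives and the p-values hold no spread between derivatives. Any other difference between the derivatives would also be called here.

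The 10 rising peaks with the smallest p were assigned to Ptger3 (log2 fold change 2.04 ± 0.14, SE, adjusted p = 9.6e-46), Skor2, a corepressor (1.72 ± 0.13), Mir5127 (1.62 ± 0.14), Anxa1 (1.37 ± 0.12), Mospd4 (1.75 ± 0.15), Rps15a, a ribosomal protein (1.84 ± 0.16), Thumpd2 (1.48 ± 0.14), Fcrl1 (1.83 ± 0.17), Kif16b, a kinesin (1.46 ± 0.14) and Six2, a homeobox factor of kidney progenitors (1.57 ± 0.15). Skor2, Mir5127 and Mospd4 lie on chromosome 18. The 10 falling peaks were assigned to Mir3963 (log2 fold change -1.60 ± 0.14, SE, adjusted p = 1.3e-25), Fam13a (-1.24 ± 0.11), Lgsn (-2.02 ± 0.18), Rab32, a small GTPase (-1.60 ± 0.15), Gm20752 (-1.52 ± 0.14), Gipc2 (-1.35 ± 0.13), Slc38a2 (-1.47 ± 0.15), 4930548G14Rik (-1.79 ± 0.18), 4930470O06Rik (-1.52 ± 0.16) and Rassf9 (-1.59 ± 0.16, and -0.97 after regional medians were removed). DESeq2 did not call the 4930470O06Rik peak (log2 fold change -1.57).

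No gene list passed for the knockdown (camera, lowest adjusted p = 0.16, for cell cycle genes, at an unadjusted p of 0.0098; adjusted p = 0.98 for each with an estimated correlation). Peaks of Blimp1 targets in lymphocytes were called higher at 8 and lower at 0 of 90 (adjusted p = 0.81). The 4 named were the cytokine gene Ifng (log2 fold change 1.13 ± 0.11, SE), the cytidine deaminase gene Aicda (0.61 ± 0.10), Ciita, the activator of MHC class II genes (0.81 ± 0.16), and Irf4 (0.72 ± 0.15). In the single contrasts, Blimp1 targets had 8 higher and 4 lower peaks at 0.5% oxygen (median -0.03) and 8 and 5 at 20% (0.00). Interferon and antigen presentation genes had 5 rising peaks and 1 falling peak of 79 (0.98), including Irf1 (0.60 ± 0.15). Epithelial genes had 4 rising and 9 falling peaks of 131 (0.81), with falls at the claudin gene Cldn3 (-1.31 ± 0.15) and at Ovol2 (-0.85 ± 0.19). Mesenchymal genes had 12 rising and 9 falling peaks of 130 (0.81), and the 4 with the smallest p all lay at N-cadherin, Cdh2, on chromosome 18 (0.89 ± 0.14 to 1.28 ± 0.15). In the pancreatic lineage, where 9 rose and 8 fell of 132 (0.98), Foxa2 peaks fell (-0.85 ± 0.12 and -1.17 ± 0.19) and a Gata6 peak on chromosome 18 rose (0.84 ± 0.12, and 0.37 after regional correction). Cell cycle genes had 8 rising peaks and 1 falling peak of 125, with Ccnd1 rising (0.57 ± 0.14; 0.35 and no longer called after regional correction) and Rrm1 falling (-0.89 ± 0.18). HIF targets had 12 rising and 13 falling peaks of 227 (0.98), with a fall at Ndrg1 (-0.50 ± 0.09) and a rise at Lox (0.81 ± 0.16; 0.53 after chromosome medians were removed). The unfolded protein response list had 10 rising and 6 falling peaks of 114 (0.98), with a rise at Herpud1 (0.91 ± 0.11) and a fall at the cystine transporter gene Slc7a11 (-1.18 ± 0.21). NF-kB genes had 7 rising and 8 falling peaks of 163 (0.81), AP-1 genes 10 and 10 of 265 (0.98), glycolysis genes 3 and 3 of 71 (0.81) and oxidative phosphorylation genes 4 and 8 of 81 (0.81). Haematopoietic markers had 2 rising peaks and 1 falling peak of 32 (0.98), endothelial markers 4 and 5 of 76 (0.81), fibroblast markers 2 and 1 of 56 (0.81) and hepatocyte markers 5 and 0 of 55 (0.84). Adjusted over the list alone, the counts were 7 and 0 for Blimp1 targets, 5 and 0 for interferon genes, 4 and 8 for epithelial, 12 and 9 for mesenchymal, 9 and 9 for pancreatic and 5 and 1 for cell cycle genes. They were 12 and 13 for HIF targets, 1 and 2 for glycolysis, 9 and 9 for AP-1, 7 and 7 for NF-kB, 10 and 6 for unfolded protein response and 6 and 8 for oxidative phosphorylation genes. For haematopoietic, endothelial, fibroblast and hepatocyte markers they were 2 and 1, 4 and 6, 2 and 1, and 5 and 0. Median and test had opposite signs for interferon genes (median -0.01, test toward higher), the unfolded protein response (-0.02, toward higher), pancreatic genes (0.01, toward lower), haematopoietic markers (-0.00, toward higher) and HIF targets (0.00, toward lower). Except at Ifng, Aicda, Herpud1, the Foxa2 peaks, the Gata6 peak, the first Cldn3 peak and 3 of the Cdh2 peaks, DESeq2 called none of the peaks named in this paragraph.

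Whole chromosomes differed between the lines at both oxygen levels. Peaks of chromosome 18 had a median log2 fold change of 0.31 at 0.5% oxygen and 0.29 at 20% oxygen in the knockdown line over the control line, and the bin median was above 0 in 36 of its 36 bins at each level. Over both levels, the medians were 0.16 on chromosome 19, 0.15 on chromosome 7 and 0.13 on chromosome 6, and -0.14 on chromosome 3, -0.16 on chromosome 16 and -0.33 over the 41 peaks of chromosome Y. Chromosome 18 held 692 of the 4677 rising peaks. After the median of each chromosome was removed, 5800 of the 8668 calls kept their direction and passed, and after that of each 2 Mb bin 5110 did.

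**Figure D4:**
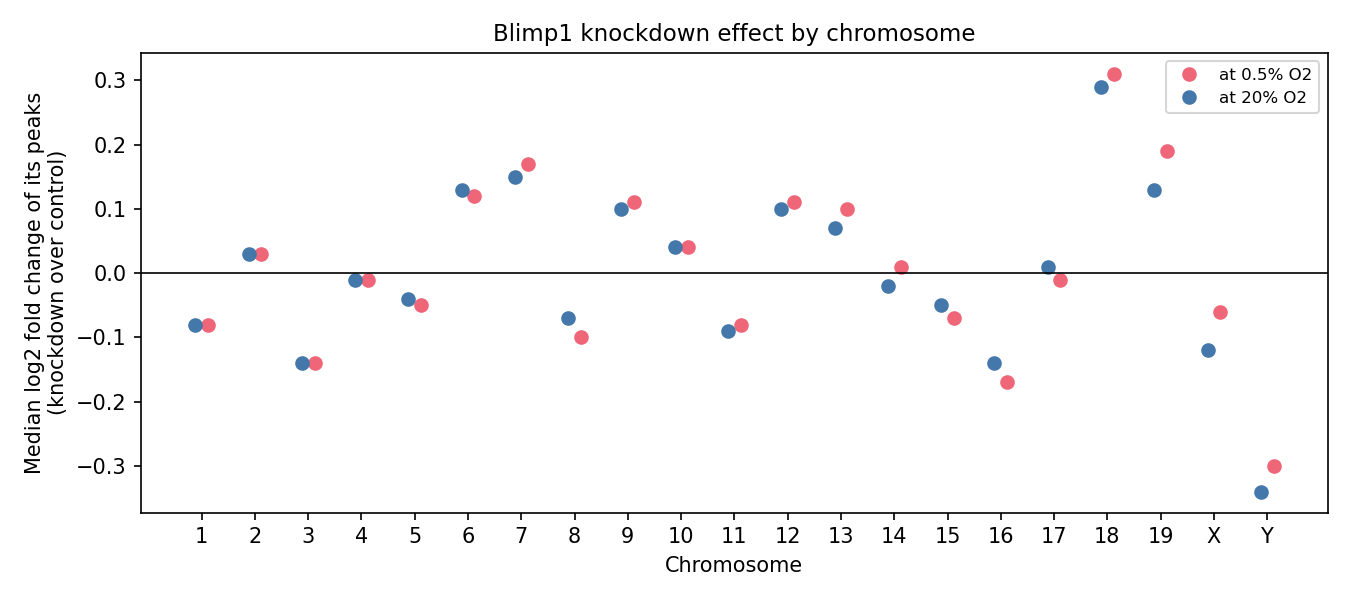
Median log2 fold change of Blimp1 knockdown over control for the peaks of each chromosome, at 0.5% and at 20% oxygen. Chromosome 18 stood at 0.31 and 0.29 and chromosome 16 below 0 at both levels.

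At single oxygen levels, 5550 peaks were higher and 4138 lower with knockdown at 0.5% oxygen, and 6113 were higher and 5551 lower at 20% (of 73416). An absolute log2 fold change of at least 1 turned these splits to 357 higher and 1079 lower, and to 878 and 1099. At 0.5% oxygen the effect moved with peak strength (Spearman 0.24): the weakest of 10 classes had a median of -0.27, with 24 higher and 371 lower, and the strongest 0.07, with 1082 and 215. The oxygen levels shared 2397 rising peaks (462 expected of independent lists) and 1596 falling peaks (313 expected), again with every peak taken as equally likely to be called. Both levels compared the same 2 derivatives, so this overlap does not separate the knockdown from other differences between them. Besides peaks named above, a peak at Eva1a rose at 20% oxygen (1.42 ± 0.11), peaks at 0610040F04Rik (-1.57 ± 0.16) and 4930567H12Rik (-1.76 ± 0.18) fell at 0.5%, and a Mir6355 peak on chromosome 18 rose at 0.5% (1.16 ± 0.11, and 0.70 after regional correction). DESeq2 called 1774 peaks at 0.5% and 3263 at 20% oxygen. The count at 0.5% was 4332 or 4687 without control replicate 1 or 2 at that level and 4136 without knockdown replicate 1. At 20% it was 6899 without control replicate 2 and 6250 or 6826 without knockdown replicate 1 or 2. With total-insert scaling the split at 0.5% was 4280 higher and 5160 lower. At Hmga2, an embryonic chromatin protein, 2 of 12 peaks were higher over both levels (0.61 ± 0.17 and 0.48 ± 0.15), and with oxygen 2 rose and 4 fell. After regional correction the first of the 2 stood at 0.40 and was not called, and none of the 4 falls was. DESeq2 called neither of the Hmga2 peaks higher with knockdown and 1 of the 6 for oxygen.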

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

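Of the tests in this part, those of the copy number of chromosome 18 and of the strength trend as the cause of the oxygen calls, and that of the correlation of regions between the lines, were chosen only after the result was seen, as was the question of background. The chromosome median correction and the thinning used below were also chosen after seeing the data.

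The oxygen effect differed between the lines at 445 peaks with a more positive and 220 with a more negative effect in the knockdown line (edgeR interaction test; 316 and 262 with total-insert scaling, 173 and 134 with loess, 111 and 129 with an absolute log2 fold change of at least 1). The test rests on the spread between technical libraries of 1 culture per group. The 5 with the smallest p and a more positive effect lay at Lrrn3 (difference of log2 fold changes 1.39), Kcnh7, a potassium channel (1.02), Tle4 (1.19), Otud7a, a deubiquitinase (1.10), and Gm5886 (1.66). The 5 with a more negative effect lay at Ptpn11, the phosphatase SHP2 (-1.13), Ddah1 (-0.91), Polr1d, an RNA polymerase subunit (-1.27), Bcas1os2 (-1.61) and Smyd2, a methyltransferase (-1.38). A Slc2a1 peak differed by -0.59. DESeq2 called 5 interaction peaks, all more positive, and called neither Gm5886 nor Slc2a1 nor any of the 5 named more negative peaks. The Slc2a1 call was lost without any 1 of the 8 libraries, and those of Ddah1 (-0.73) and Smyd2 (-1.19) without control replicate 2 at 0.5% oxygen.

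Chromosome-wide differences separated the knockdown line from the control line, among them one on chromosome 18. The tables argue against chromosome shifts as the whole cause of the knockdown calls, because 66.9% of the calls kept their direction and passed after chromosome medians were removed. A copy number difference between the derivatives may account for the shift itself: 100% of the 2 Mb bins of chromosome 18 had a median above 0 at both oxygen levels, over 3 classes of peak strength its median was 0.26, 0.29 and 0.30 from the weakest to the strongest at 20% oxygen, though 0.14, 0.32 and 0.40 at 0.5%. An effect of Blimp1 on the whole chromosome stays open, as untested, since each line was 1 derivative.

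Weaker peaks were higher and stronger peaks lower at 0.5% oxygen. A difference in depth is argued against by libraries thinned to one total, where the Spearman correlation of fold change with strength stayed at -0.18 in the knockdown line and -0.34 in the control line. The trend as the whole cause of the oxygen calls is argued against by cyclic loess, after which 81.2% of the calls kept their direction and passed. Lower signal over background at 0.5% oxygen cannot be told apart from a response of the cells: the strongest 10% of peaks held at most 36.2% of the inserts in those libraries against at least 40.3% in the others, and inserts outside peaks were not analysed here.

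Regions of 2 Mb moved together with oxygen in both lines. Clustering of peaks of like strength is argued against by the SD of bin medians, 0.273 against at most 0.104 in 100 shuffles within 10 classes of strength, though the bin medians had a Spearman correlation of -0.36 with the median strength per bin, and copy number changes arising separately in each culture by the Spearman correlation of 0.88 between the bin medians of the lines. The fall along the chromosomes remained after cyclic loess, with Spearman correlations with position of -0.41 and -0.59 in the lines, which argues against the strength trend as its cause. GC content stays open: sequence was not analysed here, and the bin medians had a Spearman correlation of only 0.22 with the number of genes named per bin. The correlation of 0.88 speaks only to changes arising separately in each culture, not to a shift common to both lines. A response of chromosome domains to oxygen is a hypothesis these data do not separate from such a shift or from GC bias. A difference in background by region was not tested.

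The 4 cultures can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. In plain comparisons without the other factor (edgeR), the oxygen split called 11112 peaks, and it was the only 1 of the 3 to call that many; the other 2 called 0 each (no other tool was run on the splits). At an unadjusted p under 0.05 the knockdown split had 2386 peaks and the crossed split 31. The knockdown split called 0 peaks, a number that all 3 splits reached, and the highest other called 11112, which follows oxygen. With no oxygen term, the oxygen effect lay in the error of the knockdown and crossed splits. Their 0 calls therefore say nothing on chance for either factor.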

How the results depend on the processing

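The corrections for regional and chromosome medians, the thinning, leaving out chromosome 18, and the list tests with loess and with a correlation estimated on all 8 libraries were chosen after seeing the data. Over both lines, the oxygen count of 31864 fell to 4763 (3359 higher, 1404 lower) with an absolute log2 fold change of at least 1 and to 10611 with DESeq2, and lay between 27847 and 31532 without 1 library. The knockdown count of 8668 was 4916 at an adjusted p of 0.01, 1053 (341 higher, 712 lower) with the fold threshold, 657 with DESeq2, and 17876 (group means) or 15301 (additive) with the 8 libraries as samples; it lay between 6132 and 8506 without 1 library. In the control line the oxygen count of 31843 was 5901 with the fold threshold and 16226 with DESeq2 (23411 to 32289 without 1 library), and in the knockdown line 29054 became 5906 and 15104 (19694 to 29458). The knockdown count at 0.5% oxygen, 9688, was 4887 at 0.01, 1436 with the fold threshold and 1774 with DESeq2, and ran from 4136 to 10148 without 1 library: 4332 and 4687 without control replicate 1 or 2 and 4136 without knockdown replicate 1 at 0.5% oxygen. At 20% oxygen, 11664 became 6523, 1977 and 3263, and 7633 after regional correction. It ran from 6250 to 12153: 6899 without control replicate 2, and 6250 or 6826 without knockdown replicate 1 or 2 at 20% oxygen. The interaction count of 665 (9590 at an unadjusted p under 0.05) was 125 at 0.01, 240 with the fold threshold, 307 with loess, 5 with DESeq2, 344 after regional correction and 250 after thinning. Without 1 library it ran from 36 to 1065: at 20% oxygen 147 without control replicate 2 and 399 or 124 without knockdown replicate 1 or 2, and at 0.5% oxygen 36 or 234 without control replicate 1 or 2 and 129 or 1065 without knockdown replicate 1 or 2. Leaving out a library leaves fewer inserts and, in the 8-library fits, a lone library assumed to vary like the others; the other causes were not tested.

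Of the 16 lists, 6 passed for oxygen, 5 with loess (adjusted p of haematopoietic markers 0.1), and 0 with an estimated correlation on the sums (lowest adjusted p 0.64) or on all 8 libraries (0.14) and 0 after regional correction (0.11). The estimated correlation left the list test 1 degree of freedom on the sums and 4 on the libraries, and so little power. No list passed for the knockdown or the interaction under any of these that was run. Replicate numbers did not pair the libraries: the differences between replicates 1 and 2 correlated from -0.109 to 0.0705 across peaks between groups. With the replicate number as a block, the 8 libraries gave 16662 calls for the knockdown over both levels, between the 17876 and 15301 without it, and 409 for the interaction against 665; no other count moved by over 1.5 times. Of 5702 alternative values for the 294 single-peak results the naming rule took, 5348 kept their direction and side of the threshold, 341 lost the call (93 of them with DESeq2 and 48 with regional correction), 12 gained it and 1 reversed: a Hmga2 peak in the control line, -0.38 with oxygen, stood at 0.02 after regional correction, and the cause was not tested. DESeq2 filtered out 19 of these single-peak results and gave no adjusted p for them, so they count neither as kept nor as lost there. The motif tests and the promoter-only and 10 kb assignments were not run.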

Other observations

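The genes in this part were chosen after their values were seen, from 1639 genes with at least 10 tested peaks. With oxygen, all 11 peaks of Malat1, a nuclear long noncoding RNA on chromosome 19, rose (median log2 fold change 0.92), as did 11 of 11 at Mir3089, 12 of 14 at Trim8 and 15 of 19 at Myh9, a nonmuscle myosin. All 20 peaks of 2610035D17Rik on chromosome 11 fell (median -1.10), as did 13 of 13 at the transcription factor gene Zfhx3 (-0.82), 11 of 11 at the fatty acid elongase gene Elovl6 (-0.80) and 15 of 18 at Fto, an RNA demethylase (-0.88). After regional medians were removed, 3 Malat1 peaks (median 0.24), 0 at Mir3089 (0.06), 6 at Trim8 and 4 at Myh9 still rose. Then 11 peaks of 2610035D17Rik (-0.37), 4 of Zfhx3, 4 of Elovl6 and 11 of Fto (-0.51) still fell.

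With Blimp1 knockdown, 10 of 12 peaks of Tmprss15, enteropeptidase, on chromosome 16 fell (median -1.09) and 0 rose; after regional medians were removed 8 fell (-0.79). At Mroh5 on chromosome 15, 7 of 12 rose (0.71) before and 7 after. At Trps1, a GATA-type repressor on chromosome 15, 12 of 23 fell (-0.58) and 8 fell after. At Rbbp8 (9 of 12 rising) and Nfatc1 (8 of 14 rising), both on chromosome 18, 1 and 2 rose after regional medians were removed.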
